A study of Chelon labrosus with 56 samples.

How the data were processed

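The series holds 56 liver RNA samples of thicklip grey mullet from 3 treatments and 3 sampling times, each on its own array. Groups, doses and times were taken from the sample labels. A description in the labels gives another length for the last sampling time than the other labels do, and the 3 weeks of the treatment and exposure time labels were used. Per the labels' protocols, RNA was extracted from liver with Trizol and column purification, copied from an oligo-dT primer, and labelled with Cy3 for 1-colour arrays. The labels describe field-collected, immature fish. Priming from the poly(A) tail makes the signal depend on where along a transcript a probe lies, so levels were compared between arrays for the same probe and never between probes.

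Each array's deposited scanner file was made with Agilent Feature Extraction 9.5.3.1, per the file headers, and holds the intensity of 34337 spots. The intensity used was the processed signal, which per the file headers had been background-subtracted and detrended within each array, with no scaling between arrays recorded. A deposited series table also holds log2 values of 10119 probes, made by the authors, with the way arrays were scaled to each other not given in the sources used here. Comparison with the scanner values showed each probe of that table centred on its median in day 1 control fish, for all 10119 probes within a tolerance of 1e-06. Column medians lay between −0.0389 and 0.0433. Of its 56 columns, 40 matched the array of their own label best, with correlations between 0.847 and 0.996 over 5211 bright probes. The other 16 matched another array better, at 0.971 to 0.995 against −0.126 to 0.351 for their own. These were the 14 exposed arrays of day 1, displaced by 1 place, and 2 low-dose arrays of week 3 that were exchanged, and 2 of the 16 thereby changed group. The scanner files, each tied to its sample, were therefore the source of all main values, and the table served as an alternative, as deposited and with its columns moved to the matching arrays.

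Control spots and the 0.13% of spots marked as outliers by the scanner software were left out, and spots of the same probe, 2 for most, were averaged. Log2 signals were reduced by each array's 75th percentile. Since a mean of 46.1% of probes was detected, the percentile was taken over the 5227 probes well above background on all arrays. Probes well above background on at least 6 arrays were tested, which were 9023 probes, 8614 of them named and 409 unnamed. Gene names are those of the array's design in the files, where 784 probes have no name and 5354 probes have a truncated one. The files give no accession for the probes, so the reference table of gene names was not used here, no coordinates are given, and names shared by gene copies may stand for several genes. The brightest probe stood for each of the 3343 names tested, except that a called gene is given by its brightest passing probe, which was not its brightest probe for 1 of 4 names between the doses on day 1 and 10 of 41 in control fish.

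All 56 arrays entered a fit of 9 group means in limma 3.58.1 under R 4.3.3, with lmFit and eBayes. Moderated tests were adjusted by the Benjamini-Hochberg method over 9023 probes at an adjusted p under 0.05. The labels name no test. Effects of each dose at each time, their means over time, the differences between doses, the differences of an effect between times (F tests) and the change in control fish (F test) were fitted as written before the data were examined. So were the alternatives, the gene lists and the rule for naming genes. Under that rule a comparison names up to 10 passing genes per direction, or 3 for differences between doses and 5 for F tests, and members of fixed lists that pass. It names the 5 genes of smallest p where fewer than 5 probes pass, and always 9 genes linked to organotin or xenobiotic response. Genes of the control fish beyond the 5 of smallest p were chosen from the passing ones after their values were seen. Lists were tested with camera with a preset correlation of 0.01, adjusted over lists and comparisons, with an estimated correlation and fry as alternatives. The lists' name patterns were adapted to the array's wording before any test value was computed. The fit was checked on simulated data, in which 200 of the 9023 real probes were changed by known amounts. For the high-dose comparison of day 1 it recovered 30% of 1.5-fold, 58% of 2-fold, 94% of 3-fold and 98% of 4-fold changes, 50 probes each, and called 4 unchanged probes. Changing 200 probes at once, with noise independent between probes, makes the adjusted threshold easier to pass than where few probes change.

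The arrays lay on 14 slides of 4 and were scanned on 4 days, with 16, 20, 16 and 4 arrays. Both batches hold several groups, so each was fitted as a fixed block, slide also as a random block with a correlation of 0.13, and values were computed within scan days. The scan day with 4 arrays held week 3 groups only. Residuals of arrays on the same slide correlated at 0.09 on average, those of the same scan day on other slides at 0.03, and the rest at −0.04. Arrays of the same group correlated pairwise between 0.949 and 0.983, so no pair was treated as a repeat of the same sample. Other alternatives were normexp background correction with an offset of 50 followed by quantile normalisation (called normexp), quantile normalisation alone, no filter, a filter at 28 arrays, array position, array weights, a block for the replicate number, only the compared groups in the fit, and, for each dose against control at each time, leaving out each array in turn. After the data were seen, 3 alternatives were added, which were the percentile over all probes, the table with moved columns, and the data without high-dose week 3 replicate 6. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.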

Results

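Liver gene expression was measured in immature thicklip grey mullet (Chelon labrosus), a coastal fish, during exposure to tributyltin (TBT). TBT is an organotin biocide once used in antifouling paints, and it is known to bind the nuclear receptors RXR and PPAR gamma. Control fish, fish at a low dose of 10 ng/L and fish at a high dose of 500 ng/L were sampled after 1 day, 1 week and 3 weeks. Each of the 56 liver RNA samples was hybridised to its own 1-colour array. There were 6 arrays in each group, except for the exposed groups of day 1, which held 7 each, while the labels' design text states 6 fish per group and time. Each array was treated as a separate fish, so the p-values measure the spread between these samples. An array had between 6310 and 12533 probes well above background. Group means of that number lay between 7136 ± 512 (SD, n = 6) in control fish of day 1 and 8370 ± 2084 (SD, n = 6) in high-dose fish of week 3. Signals are given as log2 signal relative to the array's 75th percentile, and the number of arrays limits their precision.

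High-dose fish of day 1 had less cysteine dioxygenase transcript than the controls of that day. Cysteine dioxygenase catalyses the entry step of cysteine breakdown toward taurine. Its signal averaged 1.67 ± 0.90 (SD, n = 7) in high-dose fish and 3.38 ± 0.60 (SD, n = 6) in controls, a 3.26-fold fall. The log2 difference was −1.71 (SE 0.34, limma adjusted p = 0.0224), and the gene's other probe gave −1.72. The signal was below the control mean in 7 of 7 exposed fish. Counts of fish, here and below, set each fish against the mean of the group it is compared with. An unnamed probe, CUST_10049_PI421701941, fell by 2.12 on the log2 scale (SE 0.35, adjusted p = 0.00118, lower in 7 of 7 fish). These were the 3 probes of 9023 tested that passed, all lower, and 475 probes had an unadjusted p under 0.05 where 451 are expected by chance. Named genes with the next smallest p-values did not pass. The log2 difference was −1.73 for chemokine receptor (adjusted p = 0.0679), 0.74 for hepatocyte nuclear factor alpha (adjusted p = 0.284), −1.04 for malate dehydrogenase (adjusted p = 0.341) and −0.77 for apolipoprotein b, the core protein of liver lipoproteins (adjusted p = 0.341). Tenascin c, an extracellular matrix glycoprotein, was not well above background on any control array and was so on 5 of 7 high-dose arrays. Its mean was at least 1.48-fold higher in high-dose fish (adjusted p = 0.284, higher in 6 of 7 fish). Here and below such a bound sets the bright group's mean against the lowest signal called well above background on each array of the dim group, or the probe's own signal where that is higher. The bright group's mean takes in its arrays at background as measured. The bound makes no allowance for the spread between fish, so it is not a smallest likely effect.

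Within the 3 scan days that held both groups, the cysteine dioxygenase difference was −2.13, −2.18 and −0.55, and that of the unnamed probe was −2.59, −1.78 and −1.93. On slides 1, 6, 12 and 14, which held 1 array of each group, the cysteine dioxygenase difference was −1.73, −2.59, −1.19 and 0.09. Cysteine dioxygenase gave −1.46 with slide as a fixed block and no longer passed (adjusted p = 0.175), and with scan day as a block it gave −1.69. With slide as a random block it gave −1.64 and passed (adjusted p = 0.0194), and 4 probes passed, the 3 called here among them. The gene also lost its call with array position as a covariate (adjusted p = 0.0695), with only the compared groups in the fit (adjusted p = 0.276, unnamed probe 0.0514, 3 other probes passing), and without control replicate 2, 4 or 6 or high-dose replicate 1, 2, 3 or 4 (adjusted p between 0.0644 and 0.144). The count of passing probes was 1 without control replicate 4 or 6 or high-dose replicate 1, 2, 3 or 4. It was 9 without control replicate 7, 7 without high-dose replicate 5 and 5 without high-dose replicate 7.

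**Figure D1:**
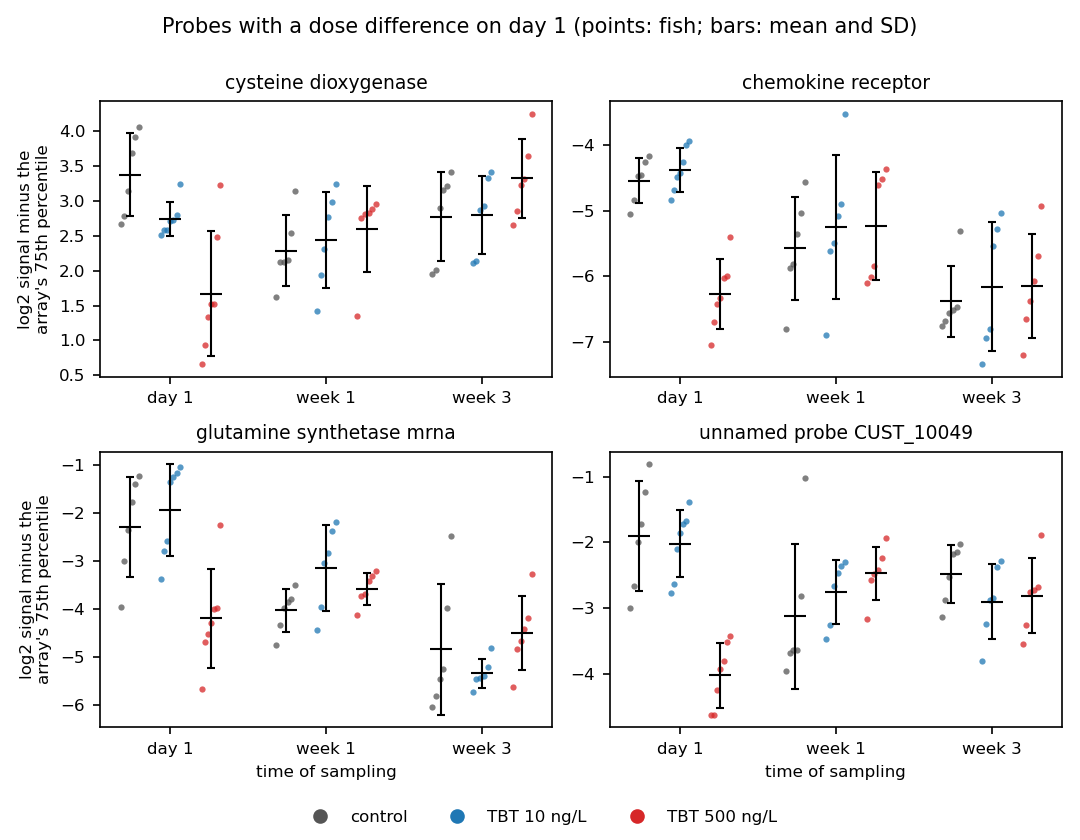
Log2 signal minus the array's 75th percentile (vertical axes) for 4 probes at the 3 sampling times (horizontal axes) in control fish and fish at 10 or 500 ng/L TBT; each point is a fish and the bars give the mean and SD of 6 or 7 fish. On day 1 the high-dose fish average 1.67 for cysteine dioxygenase against 3.38 in controls, and −6.27 for chemokine receptor against −4.37 in low-dose fish.

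Gene lists fixed before the data were examined moved by small amounts in high-dose fish of day 1. The 49 measured names of oxidative phosphorylation, which include mitochondrially encoded subunits, had a median log2 difference of −0.16, with 40 lower (camera with a preset correlation, adjusted p = 7.06e-09). Its members nd3 (−1.32) and nadh dehydrogenase subunit 6 (−0.94) did not pass singly. The 54 ribosomal protein names had a median of 0.18, with 53 higher (adjusted p = 7.06e-09), and the 37 names of RXR, PPAR and lipid metabolism had a median of −0.14, with 23 lower (adjusted p = 0.0271). None of these calls held with an estimated correlation (adjusted p = 0.512, 0.689 and 0.278). Their medians were −0.16, 0.28 and −0.07 with slide as a block, and −0.19, 0.17 and −0.16 with scan day as a block. Within scan days they ranged from −0.31 to −0.08, from −0.03 to 0.52 and from −0.30 to −0.06. No member passed over all probes, and 2 members of the lipid list passed when adjusted over the list alone. The lipid median was −0.11 with 2 dim members at their bound. On the values of the authors' table the ribosomal median was 0.06 (adjusted p = 0.0521). Of the cell type markers, the 4 erythrocyte names had a median of −0.42 (adjusted p = 0.210) and the 18 hepatocyte names one of −0.01 (adjusted p = 0.758).

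In low-dose fish of day 1 no probe passed in limma, with a smallest adjusted p of 0.999, and 313 had an unadjusted p under 0.05. Flavin containing monooxygenase 5, an enzyme of foreign compound metabolism, had the smallest p, with −0.92 (SE 0.23, lower in 6 of 7 fish). Bromodomain containing 2, whose name is truncated in the files, gave 0.81, and an immunoglobulin mu clone gave 1.41, both higher in 7 of 7 fish. A clone named afim-evh-506-043 gave 0.71, and its other probe 0.34. Sirtuin 1, a deacetylase, was not well above background on any control array and was so on 4 of 7 low-dose arrays, where it was at least 1.18-fold higher. Camera with the preset correlation called 6 lists. Medians were −0.21 for the 47 names of xenobiotic metabolism (35 lower, adjusted p = 6.96e-06), −0.20 for RXR, PPAR and lipid metabolism (24 of 37 lower, adjusted p = 4.08e-04) and −0.17 for oxidative phosphorylation (39 of 49 lower, adjusted p = 6.33e-05). They were −0.10 for glucose metabolism (11 of 15 lower, adjusted p = 0.0140), −0.06 for oxidative stress and metals (22 of 34 lower, adjusted p = 0.0444) and 0.16 for ribosomal proteins (49 of 54 higher, adjusted p = 8.00e-04). With an estimated correlation the lipid list kept its call (adjusted p = 0.0318), and the others did not (adjusted p between 0.512 and 0.835). In the order named, medians with slide as a block were −0.18, −0.21, −0.19, −0.10, −0.08 and 0.15, and with scan day as a block −0.18, −0.18, −0.18, −0.08, −0.06 and 0.16. Within scan days the lipid median ranged from −0.28 to −0.04, the xenobiotic one from −0.28 to −0.07, the oxidative phosphorylation one from −0.27 to −0.05 and the glucose one from −0.20 to −0.09. The oxidative stress median ranged from −0.32 to 0.07 and the ribosomal one from 0.09 to 0.15. Adjusted over the list alone, 2 xenobiotic names and 3 leukocyte names passed, and none passed over all probes. Cell type medians that were not called were 0.41 for connective tissue (8 of 9 higher, adjusted p = 0.117), −0.42 for erythrocyte (4 of 4 lower, adjusted p = 0.112), 0.22 for leukocyte (10 of 16 higher, adjusted p = 0.129) and 0.45 for exocrine pancreas (4 of 4 higher, adjusted p = 0.837).

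High-dose fish of week 1 had no probe past the threshold in limma (254 with an unadjusted p under 0.05, smallest adjusted p 0.985). Among the named genes with the smallest p, protein disulfide isomerase gave 1.24 (SE 0.38) and calreticulin 1.01 (SE 0.32), each higher in 6 of 6 fish and with an adjusted p of 1. Mannose-binding 2-like gave 0.82 (SE 0.21), a protein entry known by a clone number 1.01, and the immediate early transcription factor early growth response 1 gave −1.11 (SE 0.30, lower in 6 of 6 fish). On the values of the authors' table mannose-binding 2-like passed, with 0.93 (adjusted p = 0.0330). Adjusted over the list alone, 2 of the 36 names of heat shock and the unfolded protein response passed (list median 0.06, 21 higher and 15 lower, camera adjusted p = 0.210, with an estimated correlation 0.835), and 1 of the 65 names of complement, acute phase and immunity. Camera with the preset correlation called 4 lists, all with negative medians. These were −0.37 for the 5 names of the growth and thyroid axis (adjusted p = 0.0159), −0.11 for ribosomal proteins (51 of 54 lower, adjusted p = 5.85e-06), −0.13 for hepatocyte markers (15 of 18 lower, adjusted p = 0.00206) and −0.26 for connective tissue and endothelium (8 of 9 lower, adjusted p = 0.0238). None held with an estimated correlation (adjusted p = 0.590, 0.802, 0.603 and 0.603). With slide as a block the medians were −0.46, −0.01, −0.16 and −0.18, and with scan day as a block −0.37, −0.11, −0.13 and −0.26. Within scan days they ranged from −1.15 to 0.29, −0.44 to 0.22, −0.32 to 0.02 and −0.69 to 0.00. The ribosomal median turned to 0.04 with normexp background correction before quantile normalisation and to 0.02 with quantile normalisation alone or the authors' table, and the hepatocyte median turned to 0.03 with normexp.

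Low-dose fish of week 1 had no passing probe in limma either (227 with an unadjusted p under 0.05, smallest adjusted p 0.835). Lipin 1, a phosphatidate phosphatase of triglyceride synthesis, was not well above background on any control array and was so on 3 of 6 low-dose arrays, at least 1.88-fold higher (adjusted p = 0.835, higher in 6 of 6 fish). Glutamine synthetase gave 1.36 (SE 0.41), heparin cofactor ii, a thrombin inhibitor, −0.59 (SE 0.17, its other 3 probes −0.70 to −0.18), and hypoxanthine-guanine phosphoribosyltransferase, truncated in the files, −1.10, each in 6 of 6 fish. The other probe of the last gave −0.15. An lps-responsive vesicle protein was also lower in 6 of 6 fish, and was well above background on 1 of 6 low-dose and 6 of 6 control arrays. Without low-dose replicate 4 the count was 1. Ribosomal proteins had a median of −0.18 (53 of 54 lower, camera adjusted p = 3.53e-09) and the 4 erythrocyte names, led by haemoglobin beta at 0.83 and alpha at 0.76, one of 0.69 (4 higher, adjusted p = 0.0406). With an estimated correlation these became adjusted p = 0.670 and 0.590. With slide as a block the medians were −0.09 and 0.57, with scan day as a block −0.18 and 0.69, and within scan days they ranged from −0.38 to −0.04 and from 0.13 to 1.18.

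At week 3 the high-dose fish had no passing probe in limma (413 with an unadjusted p under 0.05, smallest adjusted p 0.815). N-myc downstream regulated gene 3 gave 1.08 (SE 0.28), keratin 13, an intermediate filament protein, 0.70 (SE 0.19), and allantoinase, an enzyme of purine breakdown, 0.71 (SE 0.21), each higher in 6 of 6 fish. A halibut mRNA sequence gave 0.64, and tweety 3 was well above background on 2 of 6 high-dose arrays and on no control array, at least 1.03-fold higher. Cholesterol and bile acid synthesis had a median of −0.55 over its 14 names, with 11 lower (camera adjusted p = 1.99e-06). Its members included squalene epoxidase (−1.63), farnesyl diphosphate synthase (−1.45) and cyp7, of the family of the rate-limiting bile acid enzyme (−1.19), none of which passed. Oxidative phosphorylation had a median of −0.19 (47 of 49 lower, adjusted p = 1.76e-08), xenobiotic metabolism one of 0.20 (39 of 47 higher, adjusted p = 0.0140) and connective tissue and endothelium one of 0.45 (8 of 9 higher, adjusted p = 0.0160). In every comparison the 9 connective tissue and endothelium names were 6 fibronectin, 2 decorin and 1 collagen entries. They stand for 3 of the 11 marker genes, so the list follows mostly fibronectin and its shift need not be one of a cell type. With an estimated correlation these became adjusted p = 0.278, 0.512, 0.689 and 0.603. With slide as a block the medians were −0.64, −0.26, 0.31 and 0.49, and with scan day as a block −0.58, −0.23, 0.18 and 0.54. Within scan days they ranged from −1.36 to −0.06, −0.31 to −0.13, −0.28 to 0.45 and 0.38 to 0.64. The 4 exocrine pancreas names had a median of 1.07 (4 higher, adjusted p = 0.204). Adjusted over the list alone, 1 erythrocyte name passed. Replicate 6 of this group had 12533 probes well above background, and without it the count was again 0 and the medians were −0.64, −0.15, 0.15 and 0.47. A fit with slide as a block passed 1 probe.

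Low-dose fish of week 3 likewise had no passing probe in limma (283 with an unadjusted p under 0.05, smallest adjusted p 1). A clone of the hoxba cluster was well above background on 4 of 6 low-dose arrays and on no control array, at least 2.01-fold higher. An mRNA for pif1 protein gave −2.50 (SE 0.76) and pantothenate kinase 3, of coenzyme A synthesis, −1.19 (its other 2 probes −0.59 and −0.50), each lower in 6 of 6 fish. Glycine n-methyltransferase, which consumes S-adenosylmethionine, was lower in 6 of 6 fish, and was well above background on 1 of 6 low-dose and 4 of 6 control arrays. The beta subunit of mitochondrial ATP synthase gave −0.79 (lower in 5 of 6 fish). The camera medians called with the preset correlation were −0.56 for cholesterol and bile acid synthesis (12 of 14 lower, adjusted p = 8.00e-04), −0.23 for oxidative phosphorylation (40 of 49 lower, adjusted p = 9.45e-08) and 0.47 for connective tissue and endothelium (8 of 9 higher, adjusted p = 4.48e-04). They were 0.27 for hepatocyte markers (13 of 18 higher, adjusted p = 8.88e-05), 0.10 for complement, acute phase and immunity (44 of 65 higher, adjusted p = 0.0249) and 0.17 for cell cycle and replication (14 of 19 higher, adjusted p = 0.0271). With an estimated correlation none held (adjusted p = 0.512, 0.567, 0.512, 0.512, 0.651 and 0.603). In the same order the medians with slide as a block were −0.54, −0.29, 0.56, 0.31, 0.16 and 0.16, and with scan day as a block −0.64, −0.24, 0.59, 0.27, 0.12 and 0.12. Within scan days they ranged from −1.51 to −0.10, −0.47 to −0.10, 0.18 to 1.17, 0.19 to 0.36, 0.09 to 0.25 and −0.03 to 0.28.

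**Figure D2:**
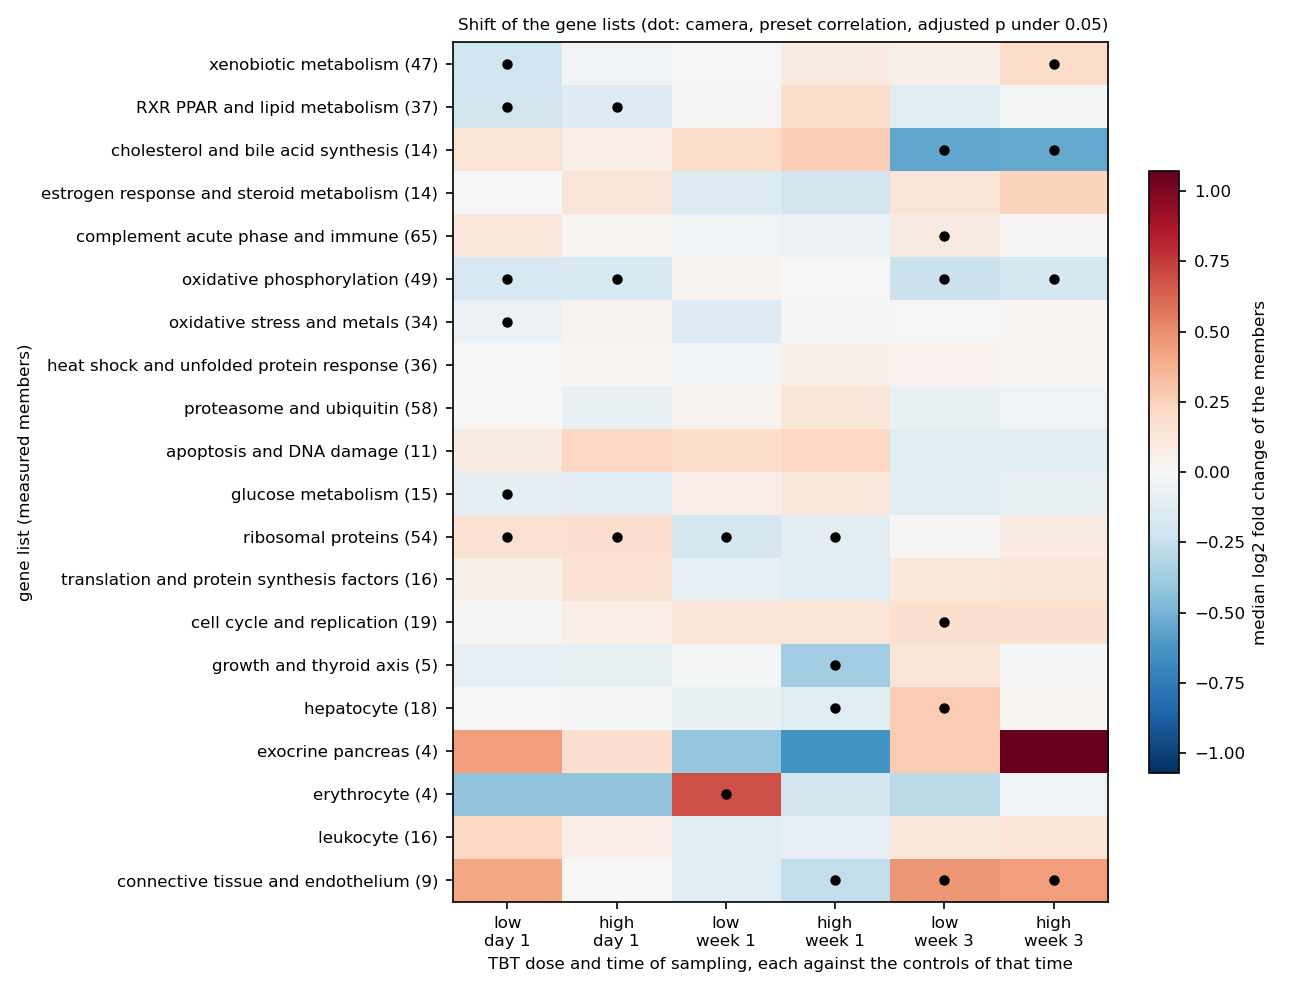
Median log2 fold change over the measured members of each gene list (rows, number of members in brackets) for each dose and time against the controls of that time (columns), as a colour from blue (lower) to red (higher); dots mark an adjusted p under 0.05 in camera with the preset correlation. The cholesterol list has medians of −0.55 and −0.56 at week 3, and the call that held with an estimated correlation is that of the lipid list in low-dose fish of day 1.

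The 20 lists and marker sets tested gave 23 calls in 120 tests of gene lists and 7 in 40 tests of cell type markers with the preset correlation of 0.01. Estimating the correlation, whose median over the lists was 0.17, left 1 call and 0 calls. Fry, which asks whether a list's genes move one way on balance, gave 0 and 0, with a smallest adjusted p of 0.754. All 30 medians kept their sign with slide or scan day as a block, and 22 kept it on every scan day that held both groups. The lists of estrogen response and steroid metabolism, heat shock and the unfolded protein response, proteasome and ubiquitin, apoptosis and DNA damage, and translation factors were called in no comparison. Nor were the exocrine pancreas and leukocyte markers. The muscle list had 1 measured name and was not tested.

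Averaged over the 3 times, neither dose had a passing probe in limma. At an unadjusted p under 0.05 there were 374 probes for the high dose and 219 for the low dose. In high-dose fish the smallest p-values were those of n-myc downstream regulated gene 3 (0.64, higher in 15 of 19 fish), a nuclear factor erythroid-derived entry (0.27), and, with many arrays at background and so without a value here, furry homolog-like and tenascin c (higher) and loc402861 protein (lower), all with an adjusted p of 1. In low-dose fish they were those of glycine n-methyltransferase (lower in 16 of 19 fish, well above background on 3 of 19 low-dose and 8 of 18 control arrays), nipsnap homolog 1 (−0.49), a pyridox clone (−0.65), homogentisate dioxygenase (−0.38) and l-threonine dehydrogenase (−0.90), each with an adjusted p of 0.999. Oxidative phosphorylation had a mean-effect median of −0.13 at the high dose (43 of 49 lower, camera adjusted p = 3.11e-14) and −0.11 at the low dose (45 of 49 lower, adjusted p = 9.45e-08). With an estimated correlation these became adjusted p = 0.278 and 0.567. At the low dose lipid metabolism (−0.08, adjusted p = 0.0158), complement, acute phase and immunity (0.08, adjusted p = 0.0159) and connective tissue (0.18, adjusted p = 0.0173) were also called, and lost their calls with an estimated correlation (adjusted p = 0.278, 0.603 and 0.603). In that order the medians were −0.12, −0.12, −0.09, 0.08 and 0.25 with slide as a block, and with scan day as a block −0.15, −0.12, −0.08, 0.08 and 0.22. Within scan days they ranged from −0.17 to −0.11, −0.15 to −0.07, −0.16 to −0.04, 0.04 to 0.19 and 0.19 to 0.49. On simulated data with known changes, the fit recovered 58% of 2-fold and 94% of 3-fold changes in the high-dose comparison of day 1, and 84% and 94% in the high-dose mean. That simulation changed 200 probes at once, with noise independent between probes, which makes the adjusted threshold easier to pass. Its shares therefore do not carry over to comparisons where few probes change.

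Genes chosen in advance for their known links to organotin or xenobiotic response did not pass at any time or dose, with a smallest adjusted p of 0.817. The 6 log2 differences from control ranged from −0.03 to 0.31 for cytochrome p4501a1, a marker of aryl hydrocarbon receptor activation, and from −0.28 to 0.49 for cytochrome p450 3a. They ranged from −0.46 to −0.12 for rxr and from −0.52 to 0.59 for pparg. For vgc, a vitellogenin and thus an egg yolk precursor under estrogen control, they ranged from −0.21 to 0.91. Metallothionein (mt) gave −0.17 to 0.10, and the lipid gene acyl- desaturase gave −2.12 to 1.99, with an SE of 1.32 or 1.37. The liver fatty acid binding protein entry fabp gave −0.13 to 0.10, and its week 1 values of −0.04 and −0.09 turned to 0.18 and 0.12 with normexp. Differences of 0.10 or less in size for cytochrome p4501a1, mt, fabp and vgc, the −0.11 of pparg at the low dose on day 1 and the 0.02 of acyl- desaturase at the high dose on day 1 (−0.50 with normexp) changed sign under at least 1 other scaling in 1 or more comparisons. Aromatase (cyp19) was well above background on at most 1 array and was not tested.

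The doses differed from each other on day 1. High-dose fish had less transcript than low-dose fish for glutamine synthetase mrna, whose enzyme fixes ammonia into glutamine, for chemokine receptor, and for the transcription factor forkhead box k1. Glutamine synthetase mrna averaged −4.20 ± 1.04 (SD, n = 7) against −1.93 ± 0.95 (SD, n = 7), a log2 difference of −2.27 (SE 0.45, adjusted p = 0.00975). Chemokine receptor averaged −6.27 ± 0.53 against −4.37 ± 0.33, with −1.90 (SE 0.38, adjusted p = 0.00975), and forkhead box k1 −5.98 ± 0.27 against −4.33 ± 1.05, with −1.64 (SE 0.34, adjusted p = 0.0106). A clone named lithmor856 and the unnamed probes CUST_10049_PI421701941 (−2.01, adjusted p = 0.00166) and CUST_10050_PI421701941 (−2.04, adjusted p = 0.00611) made up the rest of the 12 passing probes. Of 4 probes named glutamine synthetase mrna 2 passed, and the brightest gave −0.83 (adjusted p = 0.878). All 4 of chemokine receptor passed (−2.40 to −1.90), and 2 of 4 of forkhead box k1, with the others also lower. The chemokine receptor probe valued here was well above background on 5 of 7 high-dose arrays. The sizes of its differences for high-dose fish of day 1 thus rest partly on signals at background. All 12 were lower at the high dose, and 487 probes had an unadjusted p under 0.05. Each of the genes and unnamed probes valued here was below the low-dose mean in 7 of 7 high-dose fish. On slides 1, 6, 12 and 14, which held both groups, glutamine synthetase mrna differed by −1.15, −2.89, −2.75 and 0.54. Within scan days the difference ranged from −2.73 to −1.11 for glutamine synthetase mrna, −2.31 to −1.51 for chemokine receptor, −2.25 to −0.86 for forkhead box k1 and −2.14 to −1.88 for the former unnamed probe. With scan day as a block these were −2.27, −1.90, −1.64 and −2.01. Slide as a fixed block gave −2.03, −1.45, −1.81 and −2.02, and the 3 named genes no longer passed (adjusted p = 0.354, 0.454 and 0.0595), which left 2 probes, while slide as a random block kept all 12 (−2.21, −1.78, −1.69 and −2.01). On the values of the authors' table, whose columns match other arrays for the exposed fish of day 1, 2 probes passed.

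High-dose and low-dose fish did not differ by any passing probe in limma at week 1 (229 with an unadjusted p under 0.05) or week 3 (332, or 220 without high-dose replicate 6), with a smallest adjusted p of 1 in both. At week 1 the smallest p-values belonged to gadd45a, a DNA damage response gene (−1.35, lower in 6 of 6 fish), tho complex 5 (0.51, its other 3 probes 0.21 to 0.40), leucine tumor suppressor 2 (higher, well above background on 2 of 6 low-dose arrays), sphingomyelin synthase 1 (0.83) and ependymin (1.95). At week 3 the hoxba clone was at least 2.09-fold higher in low-dose fish. Limb and neural patterns gave 0.88, higher in 6 of 6 high-dose fish, as were nuclear autoantigenic sperm protein, secretion regulating guanine factor and cysteine-rich hydrophobic domain 2. These last 3 were well above background on 1, 2 and 2 of 6 low-dose arrays, so the size of their difference is not given.

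A difference of the dose effect between times was tested directly with the moderated F test. For the high dose it found 1 probe, the unnamed CUST_10049_PI421701941 (adjusted p = 0.0358), whose effect was 2.77 higher at week 1 and 1.79 higher at week 3 than the −2.12 of day 1. It passed with slide as a random block (adjusted p = 0.0211), quantile normalisation, the filter at 28 arrays, scan day or replicate number as a block, and array weights. It did not pass with slide as a fixed block (adjusted p = 0.166), normexp (adjusted p = 0.166), no filter (adjusted p = 0.0662), array position as a covariate (adjusted p = 0.105), only the compared groups (adjusted p = 0.0991) or the percentile over all probes (adjusted p = 0.0507). On the authors' table it did not pass as deposited (adjusted p = 0.315), where day 1 columns match other arrays, and passed with the columns moved. Cysteine dioxygenase had an effect 2.02 and 2.25 higher at weeks 1 and 3 than on day 1 (adjusted p = 0.0735), malate dehydrogenase 1.87 and 1.30 higher (adjusted p = 0.236), and early growth response 1 had −1.75 and −1.24 (adjusted p = 0.334). A truncated t-cell activation protein phosphatase (adjusted p = 0.236) was well above background on 0 of 7 high-dose arrays of day 1 and on at most 3 arrays of any group, so its differences are not given. At an unadjusted p under 0.05 there were 369 probes. For the low dose no probe passed in limma (249 at an unadjusted p under 0.05), and the smallest p-values were those of lipin 1, flavin containing monooxygenase 5, alcohol dehydrogenase 5, the clone afim-evh-506-043 and heparin cofactor ii, each with an adjusted p of 1.

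Over the 3 times together, more probes differed in unexposed fish than between exposed fish and controls at any time. An F test over 3 times is not of the same form as a dose comparison. Of the pairs of times only day 1 and week 3 differed by more probes (185, against 2 and 0 for the other pairs). The genes named next were chosen from the passing ones after their values were seen, apart from the 5 of smallest p, so they do not stand for a pathway. The list of RXR, PPAR and lipid metabolism had 17 names higher and 20 lower at week 3. Squalene epoxidase, a rate-limiting enzyme of cholesterol synthesis, rose from −5.45 ± 1.25 to −1.08 ± 0.42 (SD, n = 6 each), a 20.8-fold difference (log2 4.38, SE 0.77, F test adjusted p = 0.00388). 7-dehydrocholesterol reductase, which makes cholesterol in the last step, rose by 2.53 (SE 0.39, adjusted p = 0.00137), stearoyl- desaturase 5 by 3.03, fatty acid-binding brain by 2.63 and emopamil binding by 1.62. On day 1 squalene epoxidase was well above background on 5 of 6 control arrays and 7-dehydrocholesterol reductase on 4 of 6. The sizes of these 2 changes thus rest partly on signals at background. A truncated dehydrogenase reductase, well above background on 0 of 6 arrays on day 1 and 6 of 6 at week 3, was at least 2.68-fold higher. Fatty acid synthase and acetyl-coenzyme a carboxylase a (adjusted p = 0.0145 each) and hydroxymethylglutaryl- synthase 1 also passed and were higher at week 3. On day 1 they were well above background on 1, 2 and 2 of 6 control arrays, so the size of their change is not given. Acetyl-coenzyme a carboxylase a passed by 1 of its 4 probes (brightest probe, adjusted p = 0.377), and hydroxymethylglutaryl- synthase 1 by 1 of 2 (brighter probe, adjusted p = 0.0566). Apolipoprotein b fell, by −1.26 (SE 0.22, adjusted p = 0.00342) and −1.11 (SE 0.18, adjusted p = 0.00140) for its 2 leading entries, and so did malate dehydrogenase (−1.20), glutamine synthetase mrna (−2.55, its brightest probe −0.63 with adjusted p = 0.328), chemokine receptor (−1.85) and fructose-bisphosphate aldolase b of glycolysis (−1.04). Chemokine receptor was well above background on 4 of 6 control arrays at week 3, so the size of its fall also rests partly on signals at background.

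**Figure D3:**
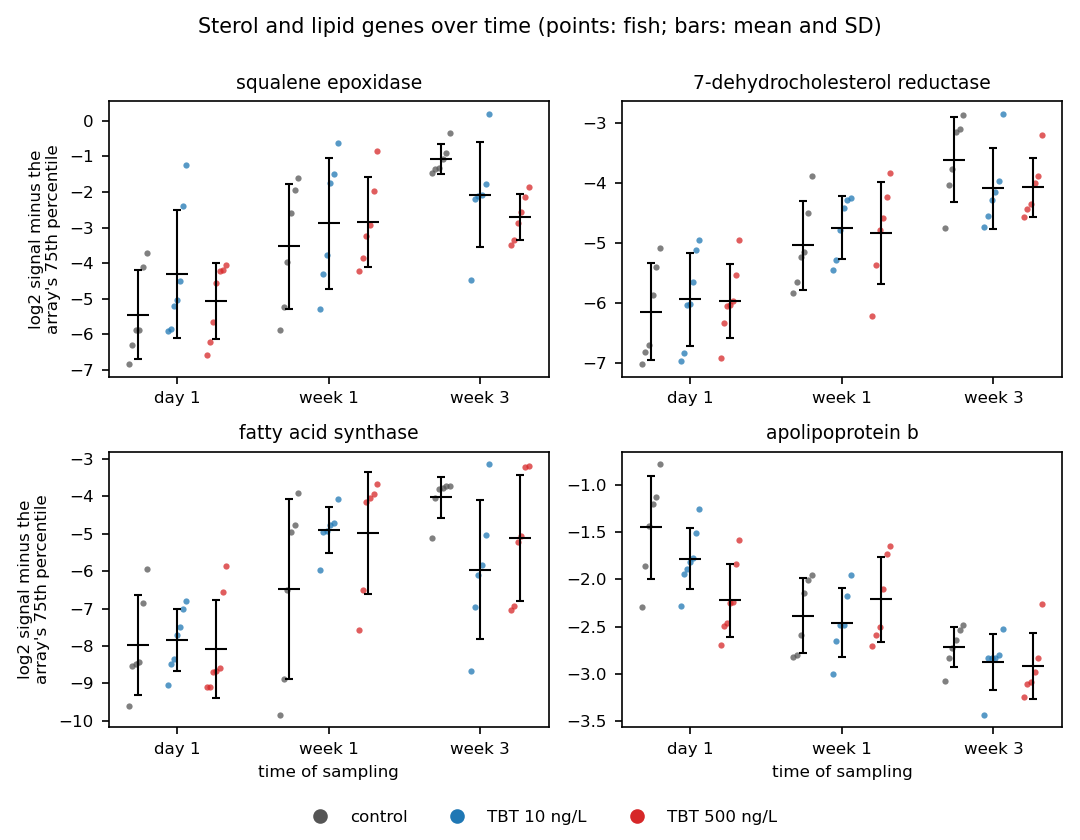
Log2 signal minus the array's 75th percentile (vertical axes) for 4 sterol and lipid genes at the 3 sampling times (horizontal axes) in control fish and fish at 10 or 500 ng/L TBT; each point is a fish and the bars give the mean and SD of 6 or 7 fish. Squalene epoxidase in control fish goes from a mean of −5.45 on day 1 to −1.08 at week 3, and apolipoprotein b from −1.45 to −2.71.

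In all, 89 probes passed in control fish across the times (1201 with an unadjusted p under 0.05), 83 of them with 41 names and 6 unnamed. Of the 41 names, 28 were higher and 13 lower at week 3. Between pairs of times, 185 probes passed from day 1 to week 3 (117 higher, 68 lower), 2 from day 1 to week 1, both lower, and 0 in limma from week 1 to week 3 (1067 with an unadjusted p under 0.05). The 14 names of cholesterol and bile acid synthesis had a median of 0.88 at week 1 and 1.60 at week 3 relative to day 1, with 11 higher. Their brightest probes passed in 3 cases over all probes and in 13 when adjusted over the list alone. In the list of RXR, PPAR and lipid metabolism, whose median was −0.11 at week 3, 5 of 37 passed and 12 when adjusted over the list alone. In the proteasome list, with a median of 0.21 (0.10 with its dim members at their bound), 1 of 58 and 10 passed. Glucose metabolism had 1 and 2, and hepatocyte markers (median −0.37), connective tissue (median −0.76) and apoptosis had 0 over all probes and 2, 2 and 1 over the list alone. The other lists had none, among them exocrine pancreas (median 2.13 at week 1 and 1.24 at week 3, 4 of 4 higher at week 3), erythrocyte (−0.48 and 0.72, 4 of 4 higher) and leukocyte markers (0.09 and −0.37, 10 of 16 lower). No list was tested with camera for the change in control fish. With slide as a fixed block 9 probes passed, of which 7 were among the 89, with slide as a random block 87, of which 80 were among them, and with only the control groups in the fit 10 passed. Squalene epoxidase then gave 3.97 and 7-dehydrocholesterol reductase 2.02 with slide as a block, and neither passed (adjusted p = 0.207 and 0.246). With scan day as a block they gave 4.47 and 2.56, and within scan days they ranged from 3.60 to 4.80 and from 1.81 to 2.98. Apolipoprotein b ranged from −1.91 to −0.72 within scan days and gave −1.19 with slide as a block. The cholesterol list's median was 1.46 with slide as a block, 1.67 with scan day as a block, and 0.89, 1.42 and 1.49 within scan days.

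The effects of the doses were compared with each other across genes, which are not independent replicates. The log2 differences of low-dose and high-dose fish correlated at 0.41, 0.55 and 0.50 on day 1, week 1 and week 3. Both doses share their controls, so 100 simulations drew unchanged low-dose, high-dose and control groups from the residuals of all 56 arrays. With the simulated controls shared by both doses, the mean correlations were 0.53, 0.50 and 0.51. The real controls of each time did not serve as controls there, so the effect of sharing these particular fish was not simulated. The covariances of 0.0486, 0.0628 and 0.0687 lay below the simulated means of 0.0747, 0.0742 and 0.0736, but inside the simulated 95% ranges. These ranges were 0.0367 to 0.126, 0.0378 to 0.128 and 0.0342 to 0.113. With the 6 controls split 3 and 3 between the doses, the mean correlations were −0.14, −0.05 and 0.01.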

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

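The rule for outlying arrays was fixed before its results were seen. So were the tests of background, noise, a single fish, and scan day for the cholesterol names. Tests of a brighter array, of a change shared by all groups and of shuffled groups were chosen after. The tests of the label order and of scan day for the day 1 probes were also chosen after. The rule was applied to 246 sets of values, each a gene or array measure in a group, and gave 15 outlying values, 3 of them on high-dose week 3 replicate 6. Chance gives about 1 in 20 sets with such a value.

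High-dose week 3 replicate 6 had 12533 probes well above background, where the nearest array of its group had 7981. A raised background was argued against by a negative-control median of 46.71 (others 41.83 to 48.62). The raw signal of these control spots had an SD of 7.63 (others 2.12 to 5125.96, 31 of them higher), so it was not unusually noisy. An array brighter by the same factor for all probes was argued against by a 75th percentile of 11.30 over probes detected on all arrays (others 10.51 to 11.97). Its median signal over all probes was higher than on any other array, at 47.33 (others 9.25 to 28.17), so its dimmer probes were brighter. On this array and at most 5 others, 3763 probes were well above background. Their median unscaled log2 signal was 4.97 here and 2.18 over the other 55 arrays. These probes were chosen for being detected here, so a higher signal was likely in advance. Lower noise as the whole cause was argued against by a 5th percentile of signal among probes above background of 17.23, within the range of the others (12.59 to 50.12), although 50 of them were higher. Of its probes, 2619 were well above background on this array alone, where no other array had more than 60 such probes. No biological explanation was tested, and the cause stays open.

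The 14 cholesterol and bile acid names had a median 1.60 higher in control fish at week 3 than on day 1, with 11 higher, 3 lower and 3 passing. A shift of whole scan days was argued against by a median of 1.67 with scan day as a block. The lowest median within a scan day was 0.89. Without each fish in turn the median ran from 1.42 to 1.86, so it did not rest on a single fish. The list was flagged on these same arrays, so medians above 0 were likely in advance and are no separate evidence of the rise. Its median was also above 0 in low-dose fish (0.85) and high-dose fish (0.61). A change with time common to all groups might account for this, with 0.61 as the smaller of the exposed medians. The labels give no condition that changed with time for all fish, so its nature was not tested.

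Probes lower in high-dose than in low-dose fish on day 1 rest on groups whose columns in the authors' table match other arrays. An order of labels shifted in the scanner files was argued against by the slides, where 8 of the 11 exposed arrays lying with a day 1 control carried its replicate number under the scanner labels and 2 under the table's labels. On 20 probes chosen without them, the arrays that would change group lay at 0.43 (high-dose replicate 7, nearer its own group on 12 probes) and 0.20 (low-dose replicate 7, on 15) of the way to the other group. Both lay nearer their own group. The other 12 arrays, each with probes chosen without it, lay between −0.26 and 0.39 of the way. High-dose replicate 7 thus lay beyond that range toward the low-dose group, so these probes do not settle its label. Within scan days the medians of the called probes were −1.60, −1.96 and −1.93. These probes were called on the same arrays, so negative medians were likely in advance and do not test scan day. Both groups had 2, 3 and 2 arrays on the 3 scan days, so a shift of a whole scan day falls on both alike.

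Groups were shuffled 100 times, the real grouping included. For the effects differing between times the groups were kept. There the residuals of an additive fit of dose and time were shuffled over the arrays instead. Both kinds are counted as groupings below. The real count was reached in 3 of 100 groupings for the high dose on day 1 (real 3, highest other 25), in 1 for the doses against each other on day 1 (real 12, highest other 4), in 2 for the high-dose effect differing between times (real 1, highest other 3) and in 1 for control fish across times (real 89, highest other 52). At an unadjusted p under 0.05, over probes with a value on every array, the real counts of these 4 results were reached in 22 (475, highest other 862), 33 (486, highest other 1237), 48 (368, highest other 1220) and 2 (1201, highest other 1237) of 100. Counts of 0 are reached by any grouping, all 100 here, and say nothing about chance, with highest other counts of 8 for the low dose on day 1, 71 for the high dose at week 1, 0 for the low dose at week 1, 10 for the high dose at week 3 and 1 for the low dose at week 3. The highest were 1 and 8 for the doses against each other at weeks 1 and 3, 27 and 2 for the high-dose and low-dose means, and 0 for the low-dose effect differing between times. The 23 calls of gene lists were reached in 66 of 100 groupings (median 25, highest 42) and the 7 of cell type markers in 42 (median 6, highest 14). Chance cannot be excluded for the list and marker calls, nor for the unadjusted counts of the first 3 results. For the high dose on day 1 the highest shuffled count was several times the real one, and the cause was not tested.

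Outlying values of single genes were these, each with the nearest value of its group in brackets. They were tenascin c −8.62 in high-dose week 1 replicate 1 (−6.73), mt 3.19 in low-dose week 3 replicate 6 (4.72), cytochrome p450 3a 1.42 in control day 1 replicate 2 (1.98) and vgc −5.46 in high-dose week 3 replicate 4 (−3.97). In control week 1 replicate 6, fabp was 6.81 (7.52) and acyl- desaturase −7.14 (−1.12), and acyl- desaturase was −1.18 in high-dose week 3 replicate 7 (1.41). In high-dose week 3 replicate 6, cysteine-rich hydrophobic domain 2 was −4.29 (−6.35) and secretion regulating guanine −4.40 (−6.70). In control fish, dehydrogenase reductase was −4.52 in week 3 replicate 2 (−5.60), the hoxba clone −7.00 in week 3 replicate 5 (−8.80) and glutamine synthetase −0.21 in week 1 replicate 1 (−1.53). The nuclear factor erythroid-derived entry was −0.86 in control day 1 replicate 7 (−0.52) and 0.17 in high-dose day 1 replicate 3 (−0.11).

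Some effects pointed opposite ways at different times, and their difference between times was tested. At the high dose the unnamed probe CUST_10049_PI421701941 passed (adjusted p = 0.0358). Malate dehydrogenase (adjusted p = 0.236) and the unnamed probe CUST_10050_PI421701941 (adjusted p = 0.374) were below control on day 1 and above at week 1 in all fish, early growth response 1 the reverse (adjusted p = 0.334), and heparin cofactor ii was below at week 1 and above at week 3 (adjusted p = 1). Lipin 1 at the low dose was above at week 1 and below at week 3 (adjusted p = 1).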

How the results depend on the processing

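All alternatives were fixed before the data were seen, except the percentile over all probes, the table with moved columns and the data without high-dose week 3 replicate 6. Across them 1981 gene results stayed the same, 11 were stronger, 31 weaker and 4 reversed, and 430 list results stayed the same and 110 were weaker. Same here means that a result passed or did not pass as in the main fit. A gene that passed in neither could count as the same after a sign change within its SE. Most named genes did not pass, so the counts do not show that values stayed alike. List medians that changed sign are among the weaker ones.

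The count of probes whose high-dose effect differed between times was 1, and it became 0 with normexp, no filter, slide as a block, array position, only the compared groups or the percentile over all probes. It became 3 with quantile normalisation, 2 on the authors' table, 4 on the table with moved columns, 4 with scan day as a block and 10 with array weights. The count for control fish across times, 89, became 56 with no filter, 9 with slide as a block, 46 with array position, 136 with scan day as a block, 188 with the replicate number as a block, 200 with array weights and 10 with only the compared groups. With slide as a random block these counts were 1 and 87, and those of day 1 were 4 for the high dose and 12 between the doses.

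For the high dose on day 1 the count of 3 became 1 with slide as a block or array position, 7 with the replicate number as a block and 6 with array weights. Leaving out an array gave from 1 (as without control replicate 4) to 9 (without control replicate 7). For the doses against each other on day 1 the count of 12 became 2 on the authors' table, 6 with its columns moved, 2 with slide as a block and 7 with array position. The high dose at week 1 gained 1 probe on the authors' table and 1 with moved columns, and the high dose at week 3 gained 1 with slide as a block. The low dose at week 1 kept 0 probes (as without control replicate 1) except for 1 without low-dose replicate 4. Without high-dose week 3 replicate 6 no conclusion changed.

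The fabp value of week 1 reversed from −0.04 to 0.18 at the high dose with normexp, and from −0.09 to 0.12 at the low dose with normexp and to 0.11 on the authors' table, as deposited or moved. Gene list calls went from 23 to 1 with an estimated correlation, 0 with fry and 57 with all matching probes, and marker calls from 7 to 0, 0 and 19. Correlations of the doses' effects became −0.14, −0.05 and 0.01 with the controls split 3 and 3, and 0.67 at week 1 with slide as a block. Residual correlations of equal replicate numbers ran from −0.16 to 0.42, and their mean was above that of other numbers in 8 of 9 comparisons (at most 0.16 against −0.03). On day 1, 8 of the 11 exposed arrays on a slide with a control carried its number, so a pairing of fish by number is neither shown nor excluded. For all of these changes the cause was not tested. Signal over background limits the dim genes, as tenascin c, lipin 1 and the hoxba clone were not well above background on any control array of their time.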

Other observations

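The idea tested here was written after the day 1 results and the change in control fish had been seen. A rule for its test was fixed before that test was run. Some genes varied far more between fish of the same group than the median residual SD of 0.46 over 2771 names. The digestive enzymes trypsinogen 2 (SD 3.51, from −7.07 to 4.10) and trypsin (SD 3.43, from −5.33 to 5.73) were among the most variable, with pentraxin (3.51), an acute phase protein, mhc ii (3.47) and nattectin precursor (3.03). Trypsin is a marker of exocrine pancreas, and the 4 pancreas names passed in no comparison as a list. The lipid genes acyl- desaturase (SD 2.45, from −7.36 to 4.09) and stearoyl- desaturase (2.36) also varied.

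Passing probes of glutamine synthetase mrna and chemokine receptor were lower in high-dose than in low-dose fish on day 1 and also fell with time in control fish. High-dose fish might therefore have moved early along the change seen in controls. The differences between doses on day 1 correlated with that change at 0.07 across 9023 probes, and 70 of 100 regroupings of the exposed day 1 arrays were as large in size (median of the others 0.10, largest 0.35). The rule fixed beforehand ranked the correlation itself, whereas its size without sign was ranked here. Within scan days the correlation was 0.12, 0.10 and −0.09. The idea was not borne out across probes, and the shared fall of these genes remains unexplained.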
